A study of Caulobacter vibrioides NA1000 with 7 samples.

How the data were processed

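The series holds 7 Agilent arrays of *Caulobacter vibrioides* NA1000 with 2 dyes. Per the labels, total RNA of the mutant was labelled with Cy5 and total RNA of the wild type, grown in the same medium, with Cy3. Cells in log phase were diluted and kept in M2G or M5G for 10 hours, per the labels' protocols. The groups were DPhoR M5G and PhoRTV M5G with 2 arrays each, and DPhoR M2G, PhoRTV M2G and DNtrX M2G with 1 array each.

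Each deposited scanner file gives the median pixel intensity of 15735 spots and of their local background in both dyes, made with Agilent Feature Extraction 10.5.1.1, per the file headers. The same files hold a log10 ratio of red (Cy5) over green (Cy3) after background subtraction and dye normalization, per the file headers. The deposited series matrix holds a log10 ratio that equalled the scanner software's at every spot (largest difference 0), so its scale and direction are those of red over green. Its column medians were -9e-04, -0.0041, 0.0077, 0, -0.0077, -0.0178 and 0.0022, and no further centring was found. How RNA was pooled and how many cultures gave the wild-type RNA are not given in the sources used here.

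The files hold no mean spot signals, which the plan named, so median spot signals and median background signals were used. Background was corrected with normexp (offset 50) and each array normalized with loess in limma 3.58.1 under R 4.3.3. Control spots had no weight in the loess and were left out after it, as were outlier spots; saturated spots were kept. The 15199 spots outside the controls held 3824 genes named by locus tag, of which 3730 matched the reference table (assembly of strain NA1000, whose coordinates matched those of the array) and 659 have a symbol. Spots of a probe were averaged, then the probes of a gene; 3570 genes have 4 probes. Further, 27 features are named by coordinates alone and 9 repeated probes have no name; these were left out of the tests. A gene was tested if a probe was well above background in a dye on at least 2 arrays, which removed 0 genes, and 0 genes lacked such a probe in a dye of a whole group.

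The arrays were fitted with limma (lmFit, eBayes) with 5 group means and 1 spread per gene, which rests on the 2 residual degrees of freedom of the replicated M5G groups. The tests were the 5 ratios against 0, PhoRTV minus DPhoR in M5G, and M5G minus M2G for each *phoR* mutant, with Benjamini-Hochberg adjustment over the 3824 genes of a comparison and a threshold of 0.05. Tests of the M2G groups assume that their single arrays vary as the replicated ones do. The wild-type signals had their own fit (4 against 3 arrays, after loess and Aquantile) and all 35 splits of the arrays into such groups. Results were computed for a pair of settings: the direction as labelled, which is the planned one, and the sign of both second M5G arrays turned (for the wild type, the other dye), which was chosen after the deleted gene and the correlations of the arrays were seen.

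The gene lists were fixed before the data were examined and cover phosphate acquisition, nitrogen assimilation, ribosomal proteins, tRNA synthetases, flagella and chemotaxis, pili with holdfast and stalk, cell cycle, heat shock, general stress, respiration, central carbon, SOS repair, sphingolipid synthesis and two-component signalling. They were filled through symbols, since the reference table has no product text, so the ribosomal, respiratory and other lists hold only genes with a symbol, and a list of TonB-dependent receptors could not be filled and was not tested. Lists were tested with camera, with a preset correlation of 0.01 and with an estimated one, and their medians set against 10000 random lists matched on intensity. For the single-array groups, only the random lists were used. These treat genes as independent, so their percentiles overstate the evidence for lists of neighbouring genes.

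Genes were named by a rule fixed before the data were examined. It names *phoR*, *phoB*, *phoU*, the pst and the ntr genes in every comparison, of which *pstS* and *ntrB* have no symbol in the reference table. In the M5G comparisons it names the 10 largest rises and the 10 largest falls past the threshold with the same sign on both arrays. In M2G it names the 5 largest each way, in the differences the 5 largest each way past the threshold, and from each list up to 4 called members. Genes named outside the rule were chosen after their values were seen. Among them are those given for the difference between the mutants, and *nasC* and *narX* in DNtrX. So are *znuL*, CCNA_01588, *ahpC* and *ahpF* where replicate arrays are compared.

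The alternatives were no background correction, an offset of 16, median centring in place of loess, the scanner software's log ratio, Aquantile and scaling between arrays, no and a strict filter on dim probes (3820 genes), the median over probes, eBayes with trend and robust settings, each replicate left out, and the slide as a block. The slide as a random block could not be fitted to the ratios with 2 residual degrees of freedom, so a fixed block of the M5G arrays was used, chosen after the data were seen. Tested on simulated data with 200 changed genes among 3824 and the spread of the turned arrays, limma recovered 55% of changes of 1 and 74% of changes of 2 on the log2 scale for DPhoR M5G, and 52% and 76% for PhoRTV M5G. It recovered 1% and 39% for DPhoR M2G, 1% and 51% for PhoRTV M2G, 2% and 52% for DNtrX M2G, and 88% and 97% for the wild type between media. With the spread of the arrays as labelled it recovered 0% for each of the 5 ratios, so a count of 0 as labelled says little about change.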

Results

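Gene expression of *Caulobacter vibrioides* NA1000 was measured on 7 Agilent arrays with 2 dyes, each holding RNA of a mutant and of the wild type grown in the same medium. The labels name 3 mutants. DPhoR lacks *phoR*, the histidine kinase gene of the phosphate-sensing PhoR-PhoB system, DNtrX lacks the response regulator gene *ntrX*, and PhoR(TV), written PhoRTV here, carries an altered *phoR* allele whose substitutions are not given in the sources used here. Cells were kept for 10 hours in M2G, labelled phosphate replete, or in M5G, labelled phosphate limited. DPhoR M5G and PhoRTV M5G had 2 arrays each, and DPhoR M2G, PhoRTV M2G and DNtrX M2G had 1 array each, so the M2G groups have no replicate check. The series title concerns cross-talk between related signalling proteins. Between 98.07% and 99.99% of the spots of an array and dye were well above background, and the number of arrays limits the precision. The labels call the second M5G arrays biological replicates without saying how their cultures were made, so each p measures the spread between these samples.

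The deleted genes were read first, as a check of the labels. On the DPhoR M2G array *phoR* (304469 to 305884 of the NA1000 reference assembly) had a log2 ratio of mutant over wild type of -2.1, and on the first DPhoR M5G array it had -2.47. On the second array labelled DPhoR M5G the value was 2, with the 4 *phoR* probes between 1.61 and 2.3, so there the labelled mutant dye held more *phoR* RNA than the labelled wild-type dye. The *phoR* probes gave 0.31, 0.16 and -0.36 on the PhoRTV M2G array and the first and second arrays labelled PhoRTV M5G, and 0.39 on the DNtrX M2G array. The deleted *ntrX* (1943552 to 1944940) had -4.08 on the DNtrX M2G array and between -1.11 and 0.44 on the other 6 arrays.

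The second M5G arrays ran opposite to the first ones across genes. The log2 ratios of the 2 arrays labelled DPhoR M5G had a Pearson r of -0.689 across 3824 genes, and those of the 2 arrays labelled PhoRTV M5G had r of -0.655. The 2 second arrays, which share slide 1, had r of 0.848 with each other, and the 2 first arrays, which share slide 2, had r of 0.839. Genes are not independent replicates, so these are descriptions without a p. The dyes in the labels are the same on all arrays, yet the *phoR* value of the second array labelled DPhoR M5G opposes its label. That leaves the direction of the second M5G arrays unsettled by the labels. Every comparison is therefore given as labelled and with the sign of both second arrays turned. The turned direction is the likely one for the array labelled DPhoR M5G, on the basis of its deleted gene; no deleted gene checks the second array labelled PhoRTV M5G, whose turned direction rests on its slide partner and on its signals. The red signal of the first array labelled PhoRTV M5G had r of 0.9895 with the green signal of the second, against 0.9164 for red with red and 0.9083 for green with green.

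**Figure D1:**
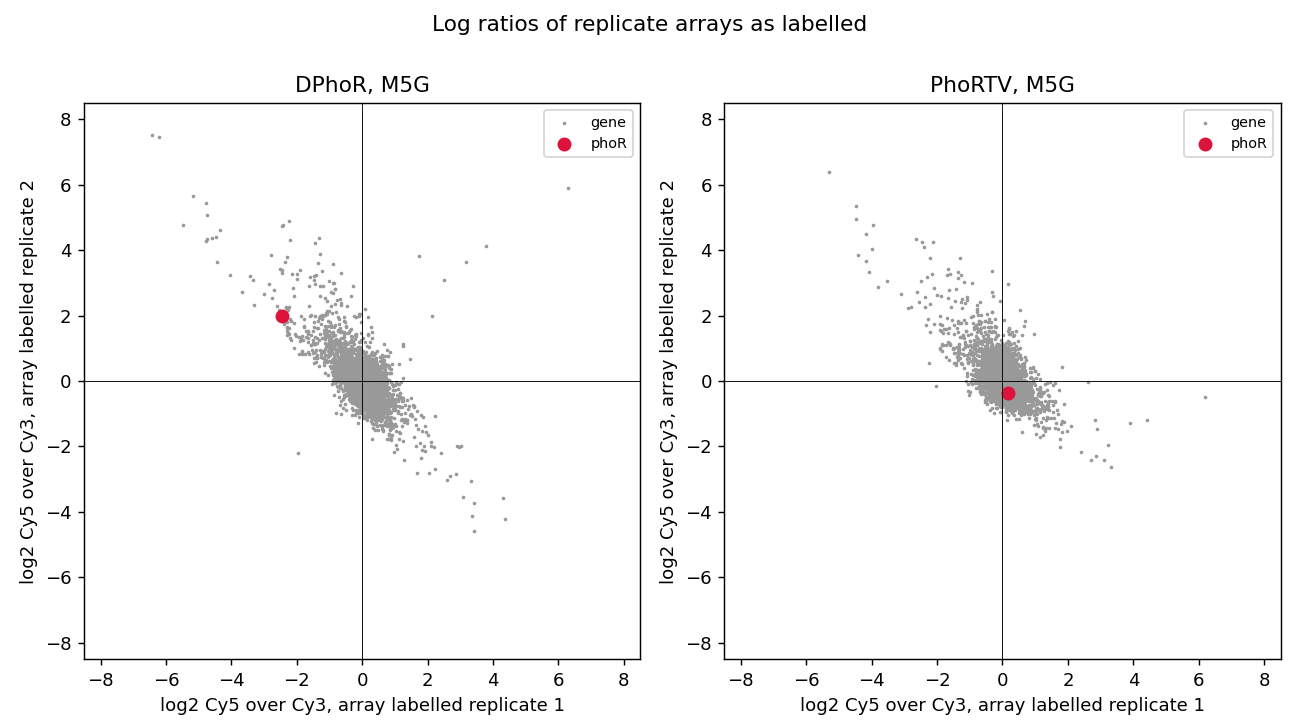
Log2 ratio of Cy5 over Cy3 per gene on the first (horizontal) and second (vertical) array labelled DPhoR M5G (left) and PhoRTV M5G (right), with each gene a point and phoR in red. The genes lie along the falling diagonal (r of -0.689 and -0.655), and phoR lies at -2.47 and 2 in the left panel.

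DPhoR in M5G against the wild type asks which genes need the kinase when phosphate is scarce. With the second arrays turned, *phoR* itself fell by 2.23 on the log2 scale (SE 0.18, n = 2 arrays, limma adjusted p 0.00462). The genes next to *phoR* were lower too: the transporter gene *pstC* fell by 2.01 (SE 0.17, limma adjusted p 0.00572), *pstB* fell by 1.96 (SE 0.23, limma adjusted p 0.013) and *pstA* fell by 1.31 (SE 0.16, limma adjusted p 0.015) on the log2 scale. Their regulator gene *phoU* fell by 1.94 (SE 0.22, limma adjusted p 0.0126), and the response regulator gene *phoB* fell by 1.87 (SE 0.28, limma adjusted p 0.0249). The largest falls were those of CCNA_00759 at -6.97 (SE 0.28, limma adjusted p 0.000928) and CCNA_00486 at -6.85 (SE 0.39, limma adjusted p 0.00212). The largest rises were those of CCNA_01093 at 4.28 (SE 0.16, limma adjusted p 0.000912) and CCNA_02741 at 4 (SE 0.3, limma adjusted p 0.00379). The other genes named by the rule rose by between 2.8 and 3.94, among them the outer membrane receptor gene *chvT* at 3.58, or fell to between -4.47 and -5.42, among them CCNA_02232 at -5.42 and CCNA_01047 at -5.12. In all, limma called 374 of 3824 genes at an adjusted p under 0.05, 143 higher and 231 lower in DPhoR, of which 266 differed at least 2-fold, and 1032 genes had an unadjusted p under 0.05. Median centring in place of loess gave 118 genes, eBayes with trend and robust settings 122, and the fit without the second DPhoR array 237. Turning only the array labelled DPhoR M5G, the one its deleted gene checks, gave 0 genes by limma here, with 333 at an unadjusted p under 0.05, and also 0 in PhoRTV M5G, in DNtrX and in DPhoR between media, with 6, 208 and 40. In that setting the DPhoR M5G means stayed the same, but the PhoRTV M5G arrays cancelled and widened the spread that all groups share. The typical SD of a gene was 0.327, against 0.244 with both second arrays turned. As labelled, limma called 0 genes, with 17 at an unadjusted p under 0.05, and *phoR* had a mean of -0.23 because its 2 arrays cancel.

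Of the 14 gene lists fixed before the data were examined, the ribosomal protein genes had the median furthest from 0 and the largest share of called members in this comparison. Of these 26 genes 24 lie between CCNA_01305 and CCNA_01332, so they are not independent of each other. Once the second arrays were turned, 21 of the 26 listed genes were lower in DPhoR in M5G and 0 higher, and 26 were lower when adjusted over the list alone; *rplW* fell by 3.61 (SE 0.64, limma adjusted p 0.0352) and *rpsC* fell by 3.33 (SE 0.33, limma adjusted p 0.00852) on the log2 scale. Their median was -2.51, and camera gave an adjusted p of 6.55e-18 with the preset correlation and an adjusted p of 0.559 with an estimated one, before adjustment p 0.1, where the nitrogen list had a lower p. Of the 10 phosphate acquisition genes 6 were lower and 0 higher, and 7 were lower when adjusted over the list alone. The 6 are those named in the comparison above, neighbours on the chromosome that include the deleted *phoR*. The list median was -1.63, and the camera p was 3.82e-06 with the preset and 0.195 with the estimated correlation. Of the 21 nitrogen assimilation genes the scanner software's log ratio gave 4 higher and 1 lower, or 10 higher and 2 lower adjusted over the list alone. In the main setting 2 were higher and 1 lower, and 7 were higher and 1 lower when adjusted over the list alone. Among them *nrtA* rose by 1.24 (SE 0.15, limma adjusted p 0.015), *nrtD* rose by 0.76 (SE 0.14, limma adjusted p 0.0396) and *gltD* fell by 0.94 (SE 0.15, limma adjusted p 0.0269), and the list's camera p was 0.0021 with the preset and 0.0779 with the estimated correlation. The 59 flagellar and chemotaxis genes had 0 called members, over all genes tested and adjusted over the list alone, and a median of 0.24; their camera p was 0.000189 with the preset and 0.381 with the estimated correlation.

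The remaining 10 lists had between 0 and 4 called members each in DPhoR in M5G, again with the second arrays turned. In the heat shock list of 13 genes 4 were lower, among them *dnaK* at -1.13 and *dnaJ* at -0.94, and 6 were lower when adjusted over the list alone, with an estimated-correlation camera p of 0.2. In the sphingolipid list of 13 genes *sgt1* at -3.2 and *sgt2* at -1.76 were lower, the same number as when adjusted over the list alone, with a camera p of 0.362. In the SOS list of 12 genes *sidA* at 1.26 and *lexA* at 0.89 were higher, with 3 higher when adjusted over the list alone and a camera p of 0.14. In the two-component list of 35 genes *phoR*, *phoB* and *chvI* at -1.42 were lower, with 1 higher and 4 lower when adjusted over the list alone and a camera p of 0.762; the list's median of 0.06 and mean of -0.03 differ in sign. The respiration list of 30 genes had *atpD* at -1.01 and *atpA* at -0.82 lower, with 0 when adjusted over the list alone and a camera p of 0.563. The central carbon list of 7 genes had *sucD* at -1.33 lower, with 2 lower when adjusted over the list alone and a camera p of 0.463; its median of 0.1 and mean of -0.25 differ in sign. The tRNA synthetase list of 6 genes had *trpS* at 2.45 higher, with 1 higher and 3 lower when adjusted over the list alone and a camera p of 0.351; its median of -0.45 and mean of 0.01 differ in sign. The cell cycle list of 43 genes had *bacA* at -0.99 lower, with 0 when adjusted over the list alone and a camera p of 0.826. The pilus, holdfast and stalk list of 35 genes and the general stress list of 8 genes had 0 called members, also when adjusted over the list alone, with medians of 0.17 and 0.1 and camera p of 0.562 and 0.654. With an estimated correlation no list of the 14 had an adjusted camera p under 0.05 in this comparison. That form of camera rests on 2 residual degrees of freedom and could hardly pass any list. The nitrogen list, with an estimated correlation of -0.023, still went from a camera p of 0.0021 to 0.0779.

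PhoRTV in M5G against the wild type asks how the altered allele acts when phosphate is scarce. With the second arrays turned, *phoR* had a mean of 0.26 (SE 0.18, n = 2 arrays, limma adjusted p 0.467). The transporter gene *pstC* fell by 1.91 (SE 0.17, limma adjusted p 0.0122) and *pstA* by 1.23 (SE 0.16, limma adjusted p 0.0294) on the log2 scale. *pstB* fell by 1.4 and *phoU* by 1.37, each with a limma adjusted p of 0.0496, while *phoB* at -1.48 (SE 0.28) missed the threshold with a limma adjusted p of 0.0656. Among called genes the largest falls were those of CCNA_00486 at -5.85 (SE 0.39, limma adjusted p 0.00528) and CCNA_01170 at -4.93 (SE 0.25, limma adjusted p 0.00491). The largest called rises were those of *chvT* at 2.98 (SE 0.22, limma adjusted p 0.00624) and CCNA_01738 at 2.75 (SE 0.23, limma adjusted p 0.00966). The other genes named by the rule rose by between 1.75 and 2.58 or fell to between -3.34 and -4.71. In all, limma called 122 of 3824 genes, 41 higher and 81 lower in PhoRTV, of which 112 differed at least 2-fold, and 801 had an unadjusted p under 0.05. Median centring gave 16 genes, and eBayes with trend and robust settings gave 0, with 779 at an unadjusted p under 0.05. With 1 array left out the count ran from 77 to 432. As labelled, limma called 0 genes, with 15 at an unadjusted p under 0.05.

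In the same comparison 12 of the 26 ribosomal protein genes were lower and 0 higher, and 25 were lower when adjusted over the list alone, with *rpsC* at -2.74 (SE 0.33) and *rplV* at -2.71 (SE 0.44) the largest falls among the called members. Their median was -1.77, with a camera p of 5.73e-18 with the preset and 0.106 with the estimated correlation. Of the 10 phosphate acquisition genes 4 were lower and 0 higher, and 6 were lower when adjusted over the list alone, with an estimated-correlation camera p of 0.267. With the scanner software's log ratio 2 of the 10 were lower, and again 6 when adjusted over the list alone. Of the 21 nitrogen assimilation genes *glnK* at 1.31 (SE 0.21, limma adjusted p 0.0496) and *glnB* at 1.1 (SE 0.18, limma adjusted p 0.0496) were higher, the same number as when adjusted over the list alone, with an estimated-correlation camera p of 0.0716. In the SOS list *recA* at 1.02 and *lexA* at 1 were higher, also when adjusted over the list alone (camera p 0.204), and in the heat shock list *lon* at 1.07 was higher, with 1 higher and 4 lower when adjusted over the list alone (camera p 0.536). In the sphingolipid list *sgt1* at -2.56 was lower, with 2 lower when adjusted over the list alone (camera p 0.439). The other 8 lists had 0 called members; adjusted over the list alone the central carbon list had 1 higher and the others 0, and their camera p with an estimated correlation ran from 0.381 to 0.924. With the preset, camera also called the phosphate, nitrogen and flagella lists (camera p 0.00025, 0.00126 and 0.000187). With an estimated correlation the lowest adjusted camera p in this comparison was 0.741.

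**Figure D2:**
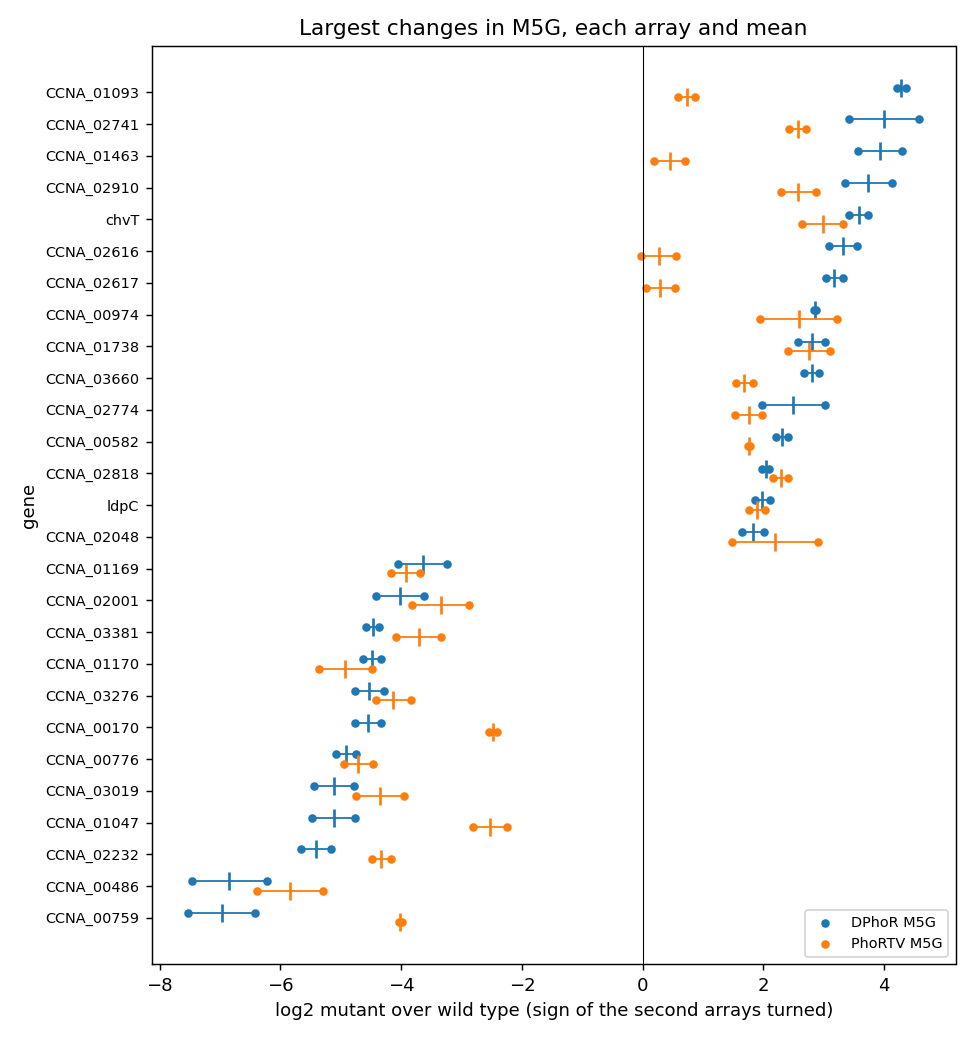
Log2 ratio of mutant over wild type (horizontal, second arrays turned) of the genes named by the rule in DPhoR M5G (blue) and PhoRTV M5G (orange), with 2 arrays as points and their mean as a bar. CCNA_01093 had a mean of 4.28 in DPhoR and 0.73 in PhoRTV, and CCNA_00759 had -6.97 and -4.01.

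The difference between PhoRTV and DPhoR in M5G asks which genes the allele and the deletion affect unequally. In the turned direction *phoR* was higher in PhoRTV by 2.5 (SE 0.25, limma adjusted p 0.0992), which missed the threshold. The difference was -3.56 for CCNA_01093 (SE 0.22, limma adjusted p 0.0538), -3.49 for CCNA_01463 (SE 0.34, limma adjusted p 0.0992) and 2.59 for CCNA_00169 (SE 0.21, limma adjusted p 0.0879). Without a slide block limma called 0 genes in the turned direction, with 133 at an unadjusted p under 0.05. As labelled, the planned direction, it called 0 genes, with 0 at an unadjusted p under 0.05. With 1 array left out the turned count ran from 1 to 22. The 2 mutants were hybridised on each of 2 slides, and with the slide as a fixed block, a paired fit chosen after the values were seen, limma called 16 genes, 6 higher and 10 lower in PhoRTV. Those lower in PhoRTV included CCNA_01093 at -3.56 (SE 0.12, limma adjusted p 0.00345), CCNA_01463 at -3.49, CCNA_02616 at -3.06, CCNA_02617 at -2.89, and, more weakly, the tRNA synthetase gene *trpS* at -2.07 and *surF1* at -1.83. Their means in DPhoR were 4.28, 3.94, 3.32, 3.18, 2.45 and 2.1, and in PhoRTV 0.73, 0.45, 0.27, 0.29, 0.38 and 0.27. Those higher in PhoRTV were CCNA_00759 at 2.96, CCNA_01047 at 2.59, CCNA_00169 at 2.59, *phoR* at 2.5, CCNA_00170 at 2.06 and CCNA_03791 at 1.24. CCNA_00759 had a mean of -4.01 in PhoRTV and -6.97 in DPhoR, so it was lower than in the wild type in both. The paired fit leaves fewer residual degrees of freedom than the 2 of the main fit. Its SE and p therefore lean more on the spread that limma borrows from all genes. The pst genes, *phoU* and *phoB* differed by between 0.08 and 0.57, with a limma adjusted p of 0.998 in the turned fit without a slide block. Of the lists, the ribosomal protein genes had a median difference of 0.48 with 0 called members, also when adjusted over the list alone (camera p 7.03e-07 preset, 0.247 estimated), and the phosphate acquisition genes had 0.22, with 0 called and 1 higher adjusted over the list alone (camera p 0.00565 preset, 0.369 estimated). With the preset, camera also called the heat shock list at 0.16 (camera p 0.00497), the respiration list at 0.09 (camera p 0.0125) and the central carbon list at 0.13 (camera p 0.0164), each with 0 called members, also when adjusted over the list alone, and with an estimated correlation their camera p were 0.151, 0.204 and 0.144.

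The log2 ratios of DPhoR and PhoRTV in M5G moved together across genes. Their means, with the second arrays turned, had a Pearson r of 0.858, a Spearman rho of 0.77 and a covariance of 0.342 across 3824 genes. Both mutants may have been set against the same wild-type RNA on a slide, and a simulation of unchanged groups that share that RNA in full gave r of 0.515 and a covariance of 0.044. Between slides, where no array is shared, r was 0.58 and 0.599 with covariances of 0.268 and 0.292 in the turned direction. As labelled these r were -0.58 and -0.599, so their sign follows from the turn, which was chosen after the correlations of the arrays were seen. The r of 0.58 needs the second PhoRTV array turned, which no deleted gene checks, so its sign is no evidence of a shared direction. The r of 0.599 needs only the second DPhoR array turned, which its deleted *phoR* calls for apart from the correlations. Its sign therefore argues for a shared direction, on 1 pair of arrays. Of the called genes 31 were higher in both mutants, against 1.53 for independent lists of those sizes, and 80 were lower in both, against 4.89. Independence leaves out the wild-type RNA that both mutants may share, so part of this excess may come from it. No gene was called in opposite directions, and 225 of the 231 genes lower in DPhoR were below 0 in PhoRTV too. As labelled the correlation of the means was 0.78, and from 0.14 to 0.49 with 1 array left out.

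DPhoR in M2G against the wild type asks what the deletion does when phosphate is plentiful. *phoR* had -2.1, the largest fall of this array, while *pstB* had 0.84, *phoU* 0.78, *pstC* 0.7, *pstA* 0.69 and *phoB* 0.57, each on the side opposite to that in M5G with the second arrays turned. By size alone the largest values were 1.48 for CCNA_00849, 1.43 for CCNA_00169, 1.28 for CCNA_00170, 1.22 for the efflux pump gene *acrB2* and 1.11 for CCNA_00848, and after *phoR* the lowest were -0.63 for *fixK* and *hutA*. The 10 phosphate acquisition genes had a median of 0.4, at percentile 100 of 10000 random lists matched on intensity (central 95% from -0.14 to 0.12). The random lists treat genes as independent, while *phoR*, the pst genes, *phoU* and *phoB* are neighbours, so this percentile overstates the evidence. With 1 array the test borrows the spread of the M5G arrays, on the assumption that this array varies like them. Limma called 0 genes with the second arrays turned, with 12 at an unadjusted p under 0.05, and as labelled 0 genes, with 0 at an unadjusted p under 0.05.

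PhoRTV in M2G against the wild type gave the smallest differences of the 7 arrays, with an SD of the log2 ratios of 0.167. *phoR* had 0.31, and *pstC* had -0.58, *pstB* -0.44, *pstA* -0.42, *phoU* -0.33 and *phoB* -0.29. By size alone the largest values were 1.99 for the regulator gene *fixK*, 1.35 for CCNA_03762, 1.34 for CCNA_01684, 1.19 for CCNA_01767 and 1.15 for *ftrB*, and the lowest were -0.82 for CCNA_03169 and -0.68 for *acrB2*. The phosphate acquisition genes had a median of -0.17, at percentile 0.07 of the random lists (-0.11 to 0.1), which again treat these neighbouring genes as independent. Under the same assumption limma called 0 genes, with 6 at an unadjusted p under 0.05 with the second arrays turned and 1 as labelled.

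DNtrX in M2G against the wild type asks which genes need the response regulator NtrX. *ntrX* had -4.08 (SE 0.3, 1 array, limma adjusted p 0.0141), and *ntrY*, the kinase gene beside it, was higher at 1.46 (SE 0.21, limma adjusted p 0.049). Among the genes called lower were genes of nitrate and nitrite use: *nrtD* at -3.44 (SE 0.2, limma adjusted p 0.0102), *nrtA* at -3.28 (SE 0.22, limma adjusted p 0.0114), *nirB* at -3.14 (SE 0.27, limma adjusted p 0.0194) and *narK* at -3.08 (SE 0.31, limma adjusted p 0.0239). *nasC* at -1.86 (limma adjusted p 0.0876) and *narX* at 0.17 (limma adjusted p 0.841), chosen after their values were seen, were not called. Among called genes the largest falls were those of CCNA_03689 at -6.24 (SE 0.34, limma adjusted p 0.0102), CCNA_00657 at -4.48 and CCNA_00210 at -4.23, while CCNA_01588 at -5.91 and CCNA_01585 at -5.76, next after CCNA_03689 by size alone, missed the threshold (limma adjusted p 0.479 and 0.315). The largest rises were those of the maltose receptor gene *malA* at 5.75 (SE 0.43, limma adjusted p 0.0141) and of its neighbours CCNA_02369 at 4.32, CCNA_02368 at 3.62, CCNA_02365 at 3.11 and *malY* at 2.58. Of the 21 nitrogen assimilation genes 8 were lower and 1 higher, and 10 were lower and 2 higher when adjusted over the list alone; the median of -0.44 lay at percentile 0.01 of random lists (-0.21 to 0.16), and camera was not run on a single array. The 8 include the deleted *ntrX* itself, and the others lie close together between CCNA_00645 and CCNA_00652. The random lists treat genes as independent, so the percentile overstates the evidence for the list. *pstC*, *pstA*, *pstB*, *phoU* and *phoB* lay between -0.49 and 0.16. This array is not one of the turned ones, but its test borrows their spread: with them turned limma called 61 genes, 12 higher and 49 lower, with 469 at an unadjusted p under 0.05, and as labelled 0 genes, with 123 at an unadjusted p under 0.05. In the turned direction median centring left 2 of the 61 calls, eBayes with trend and robust settings 31 and the strict filter 40, and with an M5G array left out the count ran from 96 to 158.

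**Figure D3:**
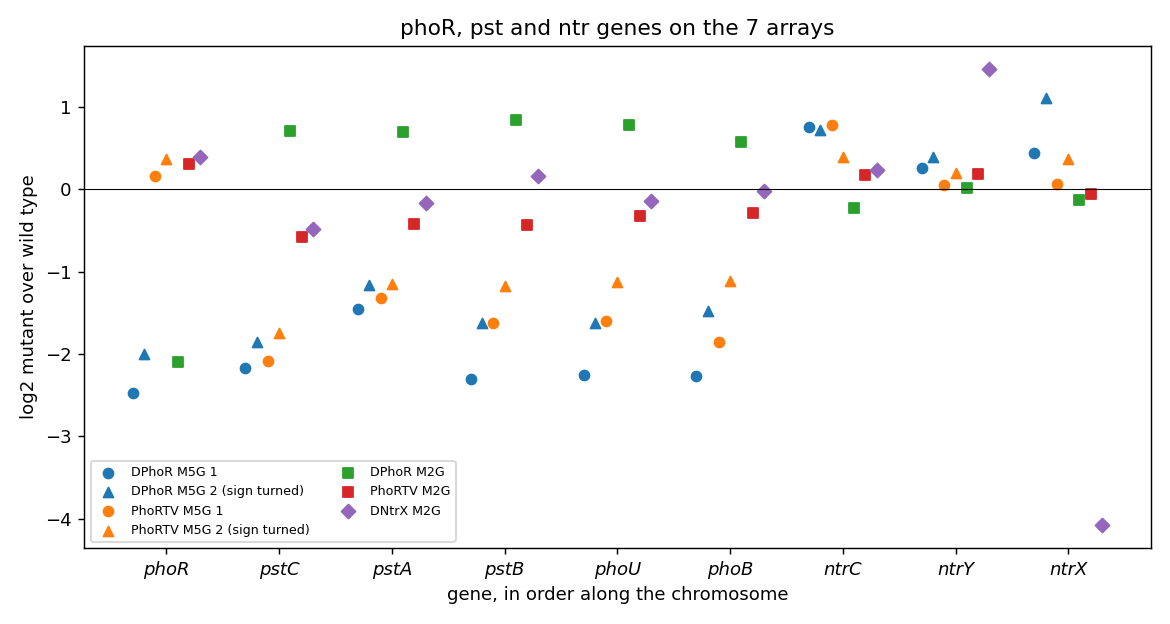
Log2 ratio of mutant over wild type (vertical) of the phoR, pst, phoU, phoB and ntr genes on each of the 7 arrays, with the sign of the second M5G arrays turned. The pst genes lie below 0 on the 4 M5G arrays and between 0.69 and 0.84 on the DPhoR M2G array, and ntrX lies at -4.08 on the DNtrX array.

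The effect of the *phoR* deletion was compared between media. In the turned direction the effect on *phoR* itself differed by -0.14 (SE 0.31, limma adjusted p 0.909). The effect in M5G minus that in M2G was -7.17 for CCNA_00759 (SE 0.49, limma adjusted p 0.0132), -5.86 for CCNA_00169 (SE 0.25, limma adjusted p 0.00783), 4.67 for CCNA_01093 (SE 0.27, limma adjusted p 0.00954) and 3.82 for *chvT* (SE 0.38, limma adjusted p 0.0253). Among the pst genes *pstC* differed by -2.71 (SE 0.3, limma adjusted p 0.0359), while *pstA*, *pstB* and *phoU* each had a limma adjusted p of 0.0604. In all, limma called 36 genes, 10 with a higher and 26 with a lower effect in M5G, and 488 had an unadjusted p under 0.05. Median centring gave 10 genes, eBayes with trend and robust settings gave 0, with 427 at an unadjusted p under 0.05, and with an M5G array left out the count ran from 95 to 218. As labelled it called 0 genes, with 0 at an unadjusted p under 0.05.

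The effect of the PhoRTV allele was compared between media in the same way. In the turned direction *pstC* differed by -1.33 (SE 0.3, limma adjusted p 0.361) and *phoB* by -1.19 (SE 0.48, limma adjusted p 0.856). Limma called 0 genes, with 224 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0667, and as labelled 0 genes, with 0 at an unadjusted p under 0.05. In the turned direction scaling between arrays gave 5 genes and the scanner ratio 4, and with an M5G array left out the count ran from 11 to 74.

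As labelled, the 2 second M5G arrays work against the first ones, and the lists were tested in that direction too. None of the 14 lists had a called member in DPhoR or PhoRTV in M5G or in their difference, also when adjusted over the list alone. The ribosomal protein genes had medians of 0.5 in DPhoR (camera p 0.0683 preset, 0.727 estimated) and 0.4 in PhoRTV (0.316 and 0.846), and the phosphate acquisition genes had -0.21 (0.263 and 0.685) and -0.17 (0.287 and 0.699). With the preset, camera called the flagella, pili and cell cycle lists in DPhoR, with medians of -0.25, -0.16 and -0.15 and camera p of 1.28e-07, 0.000599 and 0.000181. In PhoRTV it called the same lists, at -0.1, -0.12 and -0.19 (camera p 0.000919, 0.000425 and 5.03e-06), and the two-component list at -0.16 (camera p 0.000708). In the difference it called the flagella list at 0.11 (camera p 0.00401) and the SigT list at -0.27 (camera p 1.13e-07). With an estimated correlation none of these passed after adjustment, and the lowest adjusted camera p was 0.655 in DPhoR and 0.451 in PhoRTV. If the second arrays are reversed, M5G means as labelled hold the disagreement of the replicates and not a mutant effect. With them turned, the flagella, pili and cell cycle lists had medians of 0.24, 0.17 and -0.04 in DPhoR. In DNtrX the nitrogen assimilation list had 0 called members, with 1 higher and 8 lower when adjusted over the list alone. For the wild type, 25 ribosomal protein genes were lower in M5G, 4 phosphate acquisition genes were higher and 2 lower, and 3 nitrogen assimilation genes were lower and 0 higher.

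The wild-type signals of the 7 arrays were compared between M5G and M2G, which asks how the wild type responds to scarce phosphate. With the wild type read from the other dye on the second arrays, the pst genes rose in M5G, *pstB* by 2.71 (SE 0.16, n = 4 and 3 arrays, limma adjusted p 2.04e-05), *pstC* by 2.46 (SE 0.22, limma adjusted p 0.000105) and *pstA* by 1.95 (SE 0.12, limma adjusted p 2.32e-05). *phoB* rose by 2.74 (SE 0.28, limma adjusted p 0.000176) and *phoU* by 2.66 (SE 0.18, limma adjusted p 2.69e-05), while *phoR* moved by 0.03 (SE 0.21, limma adjusted p 0.915). The largest rises were those of CCNA_00759 at 7.9 (SE 0.11), CCNA_00486 at 7.35 (SE 0.15) and CCNA_00169 at 6.98 (SE 0.13), and the largest falls those of CCNA_00531 at -4.37 (SE 0.12) and *hutA* at -4.29 (SE 0.21). Of the 26 ribosomal protein genes 22 were lower in M5G and 0 higher, of the 10 phosphate acquisition genes 6 were higher and 2 lower, and of the 21 nitrogen assimilation genes 7 were lower. In all, limma called 1797 of 3824 genes, 852 higher and 945 lower in M5G, and as labelled 1695, 779 higher and 916 lower. As labelled *pstB* rose by 2.01 (SE 0.55, limma adjusted p 0.0218) and *pstC* had 1.57 (SE 0.72, limma adjusted p 0.113). These are signals of separate arrays and not ratios within an array, and the wild-type signals of a slide were so alike (r of 0.9942 on slide 2 and 0.9978 on slide 3) that they may be 1 RNA, in which case the p is too small. With the signals of a slide and scan averaged first, 693 genes were called turned and 480 as labelled.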

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

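The tests of why the second M5G arrays run opposite to the first, with the tests of genes raised at least 8-fold in the wild type, were chosen after the results were seen.

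The direction of the second M5G arrays was weighed first. An exchange of the dyes against the labels was tested on the array labelled DPhoR M5G by its deleted gene, whose log2 ratio of red over green was 2 where the label calls for a value below 0. For the second array labelled PhoRTV M5G, the red signals of the slide's 2 arrays were more alike than the green ones by 0.043 in r, while on the other slides the green signals were the more alike ones, so a reversal is likely there too. A mutant effect that reversed between cultures would leave *phoR* low in red, against the 2 measured, and a turn made by the normalization used here is argued against by r of -0.585 in the scanner software's own ratios. The zinc-responsive gene *znuL* did not follow a plain reversal, with 6.28 on the first and, turned, -5.89 on the second array labelled DPhoR M5G. Nor did CCNA_01588, with 3.79 and -4.12. Both were chosen after their values were seen. They also differed between the PhoRTV M5G arrays, turned (6.19 and 0.49 for *znuL*, 4.43 and 1.19 for CCNA_01588), and had -4.76 and -5.91 in DNtrX M2G. Genes that vary this much between arrays cannot decide the direction. Whether tubes or records were exchanged was not tested.

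Wild-type signals as labelled had 1 array far from the other 3 of M5G in *phoR* (gap over range 0.909) and in *ntrX* (0.878), above the 95% critical value of Dixon's test for 4 arrays. In both genes it was the second array labelled DPhoR M5G, whose direction is in doubt, with the lowest *phoR* and the highest *ntrX* signal. With the other dye read as wild type the gaps were 0.808 and 0.22, below the critical value, and chance picks out about 1 in 20 groups.

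The effect of the *phoR* deletion differed between M5G and M2G by limma's test of the difference in 36 genes with the second arrays turned, and in 30 of them the sign was opposite in the 2 media. The differences were 4.67 for CCNA_01093, 4.43 for CCNA_02741, 4.31 for CCNA_02910, 3.82 for *chvT* and 3.53 for CCNA_01463. They were -7.17 for CCNA_00759, -7.12 for CCNA_00486, -5.86 for CCNA_00169, -5.83 for CCNA_00170 and -5.7 for CCNA_01047. These genes were selected for a large difference, which favours opposite signs, and several M2G values lay near 0 (0.2 for CCNA_00759, 0.28 for CCNA_00486, -0.24 for *chvT*) with 0 genes called there, so a reversal of sign is not shown. CCNA_00169 and CCNA_00170 lay further from 0 in M2G, at 1.43 and 1.28, against -4.43 and -4.54 in M5G. Their signs were opposite on the arrays measured, but a single M2G array has no replicate check. The M2G side is 1 array on another slide, so slide and medium are confounded here, and the medium stays an open explanation beside the slide.

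The genes that the wild type raised at least 8-fold in M5G (30 genes, from slides 2 and 3) were lower in both mutants in M5G. This list was a second threshold, taken after the planned 2-fold list showed no shift on slide 1 and after its top genes had been seen, so it is a hypothesis only. On slide 1, whose wild-type RNA did not define the list, its median was -2.75 in DPhoR and -2.33 in PhoRTV with the sign turned, which argues against chance from shared wild-type RNA and is in line with mutants that lack part of this response. In M2G the list median was 0.3 in DPhoR, while that of -0.07 in PhoRTV lay just below the random lists (2.5th percentile -0.06). Both M2G arrays are on slide 3, whose wild-type signals helped to define the list. Picking genes for a low wild-type signal there pushes their ratios up. These medians therefore cannot decide whether the genes fall in any medium, and a fall in M2G stays open. Only the slide 1 values depend on the turned direction: on slide 2, which is not turned, the medians were -3.38 in DPhoR and -2.58 in PhoRTV, but that slide helped to define the list.

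Features named by coordinates alone, which no comparison used, differed at least 2-fold on both DPhoR M5G arrays (turned) for 2 of them, at 3952691 to 3953302 (-1.88 and -2.33) and 609287 to 610438 (-1.91 and -1.3), and on the DNtrX array for 4. Of 77 negative control spots 0 did so, which checks the background and not how often genes change. On the DNtrX array 225 of 3824 genes differed at least 2-fold. All 27 of these features share an end with a gene of the reference table. No explanation was tested.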

How the results depend on the processing

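The turned direction, the fixed slide block, the averaged wild-type signals and the arrays left out for doubt were chosen after the data were seen; the cause was not tested where none is named.

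As labelled, limma's count stayed 0 in the 8 ratio comparisons under every processing listed before the data were seen. Turning both second M5G arrays gave 374, 122, 61 (DNtrX) and 36 genes (DPhoR between media) where the labels gave 0. Turning only the array labelled DPhoR M5G gave 0 in DPhoR M5G, PhoRTV M5G, DNtrX and DPhoR between media, and reversed 8 of the 20 PhoRTV M5G genes named for the largest changes: *ldpC* -0.13, CCNA_00582 -0.01, CCNA_00486 0.55, CCNA_01170 0.43, CCNA_00776 0.24, CCNA_03019 0.4, CCNA_02232 0.16 and CCNA_00759 0.03. Among called list members *rpsC*, *rplV*, *glnK*, *lon* and *lexA* changed sign too. By construction the PhoRTV arrays then cancel, and they widen the spread that all groups share.

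With both turned, median centring in place of loess gave 118 genes in DPhoR M5G, of which 117 were among the 374, 16 in PhoRTV M5G (3 higher, 13 lower), 2 in DNtrX (0 higher, 2 lower) and 10 in DPhoR between media. The trend and robust setting gave 122, 0, 31 and 0. The strict filter gave 40 in DNtrX. The difference of the mutants rose from 0 to 1 with the scanner ratio and 1 with the median over probes; PhoRTV between media rose from 0 to 4, 5 (scaling) and 1. The fixed slide block gave 1599, 1429, 690 (DNtrX, 127 as labelled), 16 (mutant difference), 261 (PhoRTV between media) and 824 (DPhoR between media). Except for the 16, this block takes slide-to-slide variation of the ratio itself out of the spread, so these counts are too large for their use. The planned random slide block was not run for the ratios. Each M5G slide holds 1 array of each mutant, so for the mutant difference the fixed block is a paired analysis, with 16 calls.

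Leaving out each replicate, which leaves 1 array assumed to vary like the others, gave 237 to 488 genes in DPhoR M5G, 77 to 432 in PhoRTV M5G, 0 to 1 in DPhoR M2G, 96 to 158 in DNtrX, 1 to 22 in the mutant difference, 11 to 74 in PhoRTV between media and 95 to 218 in DPhoR between media. The lowest DPhoR M5G count was without its second array and the lowest PhoRTV M5G count, 77, likewise.

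Wild-type counts ran from 1090 to 1760 as labelled and from 1358 to 1803 turned with an array left out. Averaged signals gave 480 and 693, the random slide block 2209 and 2828, and without the second M5G arrays 2335. The correlation of the mutants, 0.78 as labelled, ran from 0.14 to 0.49 with an array left out; turned, it ran from 0.77 to 0.8, and genes called in neither comparison gave 0.75.

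Of 1872 values of named genes under alternatives, 1691 kept direction and side of the threshold, 137 lost and 28 gained a call. Of 126 list tests 24 lost their call, mostly with the estimated correlation. By the background flag 0 genes were dim throughout a group, but this flag does not mark absent RNA. All 4 probes of the deleted *phoR* on the DPhoR M2G array passed it in the mutant dye (mean signal 285). So did all 4 of the deleted *ntrX* on the DNtrX array (mean signal 218). How far such a floor shrinks large falls is not known.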

Other observations

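The tests of the 2-fold wild-type list, of the NtrX list and of other splits of the arrays were planned before their results were seen; reading medians near 0 as undecided was set after these values were seen, and the values that follow from no test were chosen after they were seen.

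The planned test of whether genes raised in the wild type by scarce phosphate are lower in the mutants took the 285 genes raised at least 2-fold on slides 2 and 3. On slide 1, with the sign turned, their median was -0.03 in both mutants, at percentiles 25.69 and 27.14 of random lists. The predicted shift was therefore not found on slide 1, and by the bound set beforehand the hypothesis of mutants that lack part of the response would have failed at this threshold. Since 144 genes were below and 141 above 0 in DPhoR, and 145 and 140 in PhoRTV, the median was afterwards taken to decide nothing, neither for that hypothesis nor for chance from shared wild-type RNA. On slide 2, which helped to define the list, the medians were -0.03 in DPhoR (percentile 48.61) and -0.15 in PhoRTV (percentile 0), so only PhoRTV lay below the random lists there. The 8-fold list, which did shift, was the second of 2 thresholds tried. The 317 genes lowered at least 2-fold in the wild type were also lower in the mutants in M5G, with medians of -0.34 and -0.55 in DPhoR and -0.1 and -0.33 in PhoRTV. In M2G their medians were -0.07 in DPhoR (percentile 0.03) and -0.03 in PhoRTV (percentile 0.26), closer to 0 but also low among the random lists. Both M2G arrays are on slide 3, which helped to define the list. Picking genes for a high wild-type signal there pushes their ratios down. Whether the shift is particular to M5G is therefore not decided, and no explanation of the shift was tested.

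A planned hypothesis was that the PhoR(TV) allele acts on genes that need NtrX, as cross-talk would. The 168 genes other than *ntrX* that were at least 2-fold lower in DNtrX had medians of PhoRTV minus DPhoR in M5G of 0.05 on slide 2 and 0.03 on slide 1, at percentiles 42.56 and 85.62, inside the central 95% of random lists on both slides, where the bound set beforehand asked for values above it. The predicted rise was not found. As 91 and 88 of the 168 genes were above 0, the medians were afterwards taken to decide nothing, and a comparison list of 56 genes higher in DNtrX, meant to show genes that vary on every array, had medians of 0.01 and 0. Cross-talk through a few of these genes, or through protein phosphorylation without a change in RNA, was not tested.

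Chance was tested as the source of the wild-type difference between media by the 35 splits of the 7 arrays. Only 1 split, the real one, gave as many genes, with 1695 as labelled and 1797 turned, and the highest other split gave 1. Every other split mixes the media, so a large difference between media would itself keep its count low. With 35 splits the real one can stand out at 1 in 35 at best. That argues against chance, without excluding it, if the 7 wild-type signals are separate RNAs. If the signals of a slide are 1 RNA, too few splits remain for this test, and chance is not excluded by it. Slides 2 and 3 hold 1 medium each, but slide 1 holds both, in separate scans. Within slide 1, with the second arrays turned, the difference was 8.1 for CCNA_00759, 2.35 for *pstB* and -4.53 for CCNA_00531, against 7.9, 2.71 and -4.37 over all 7 arrays. The slide alone therefore does not account for these genes. The scan stays confounded there, and so does the dye, since the turned wild type is read from red in M5G and from green in M2G.

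Replicate arrays were least alike in a small set of genes, with the sign turned. *znuL* had 6.19 and 0.49 in PhoRTV M5G and -4.76 in DNtrX M2G. *ahpC* had 0.17 and -2.97, and *ahpF* -0.34 and -3.36, in PhoRTV M5G.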
